A study of Mus musculus with 8 samples.

How the data were processed

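RNA was measured in a hybrid mouse embryonic stem cell (ESC) line, F1-21.6, and in 1 neural progenitor cell (NPC) clone derived from it. The line carries a 129Sv-Cast/EiJ background and was grown on mouse embryonic fibroblast feeders with leukaemia inhibitory factor, per the labels' protocols. Total RNA was depleted of ribosomal RNA with Ribo-Zero and made into ScriptSeq v2 libraries, which were read as 50 bp single ends. Each cell type had 2 biological replicates, and each of these had 2 technical libraries, which gives 8 libraries. Technical libraries were not counted as independent in the intronic test, and whether the authors' exon test combined them is not given in the sources used here. The p-values of the main intronic test measure the spread between these 2 and 2 biological replicates. With a replicate left out, they rest on the spread of the other group alone, and the lone sample is assumed to vary alike.

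The authors deposited 2 tables. The first holds exon values of 20596 genes, of which 84 had no name and were left out. It gives the log2 fold change of NPC over ESC and an adjusted p-value from the authors' own comparison, and RPKM pooled over all libraries of a cell type by the authors. DESeq2 1.10.0 and genome build mm9 are named in the submitters' processing notes. The aligner, the read counter and the annotation are not given in the sources used here, nor is whether counting used strand or how it treated reads shared by near-identical copies. Of the exon genes, 18213 had an adjusted p-value in the deposited table, and 2383 had none and stayed out of all counts of calls. No replicate values come with the exon table, so no standard error or spread stands beside its levels. Among 10290 genes above 1 RPKM in both cell types, the log2 ratio of the authors' RPKM exceeded the deposited log2 fold change by a median of 0.14 (SD over genes 0.0422).

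The second table holds intron values of 18719 genes (64 unnamed and left out), with 1 value per biological replicate in which the authors had combined the technical libraries. Its header names no unit, and the RPKM unit of these deposited values was inferred from the values themselves. In genes with reads, the values were whole multiples of a step set by intron length and a column denominator, within a tolerance of 0.001 reads. Whole reads came back for all 18447 genes above 0. A single intron length solved 16937 genes, and for 1510 genes several lengths did, of which the largest that fitted the intron span was taken. A further 272 genes were at 0 in every column. The column denominators were 5767704 and 6500767 reads in ESC replicates 1 and 2, and 5792056 and 5186790 in NPC replicates 1 and 2. Median recovered reads per gene were 76, 67, 119 and 71 in the same order. A gene with 10 kb of introns and 0 reads can lie as high as 0.0520, 0.0461, 0.0518 and 0.0578 RPKM (the level of 3 reads), which covers counting error only. Recovered reads were used to describe depth, background and Y-linked signal, and for 1 alternative model.

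For exons, the authors' fold changes and adjusted p-values were read as deposited, for named genes with a mean of at least 1 RPKM over both cell types, at a threshold of 0.05. For introns, log2(RPKM + 1) of genes with a mean of at least 1 RPKM was tested with limma 3.58.1 in R 4.3.3, ESC replicates against NPC replicates, with Benjamini-Hochberg adjustment. Its fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes. The mean-variance trend of limma was switched on after the values were available and before any call was seen, and the choice without it is among the alternatives. Replicate numbers were not used to pair samples.

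Lists of genes were fixed before the data were examined: 39 lists of cell type markers, pathways, complexes and chromosomal families. Each list got the number of tested members called higher and lower, over all genes and adjusted over the list alone, and its median log2 fold change. For the exon table the p-values behind the second count were recovered from the adjusted values and are upper bounds where those tie. The median was placed among 10000 random lists of the same size matched on mean expression in 20 bins, 2-sided, with Benjamini-Hochberg adjustment over the lists with at least 3 tested members. On introns, camera was run with a preset correlation of 0.01 and with an estimated correlation. The estimated correlation rests on 2 replicates per cell type, so a list that does not pass with it is not shown to be unchanged. The random lists and the preset correlation make little or no allowance for members that vary together.

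The exon and intron fold changes were compared across genes with Pearson and Spearman correlations. Genes are not independent replicates in this or in any comparison across genes here. X-linked and autosomal genes were compared by the difference of their medians, with 100000 permutations of the chromosome label, 2-sided. Adjacent tested genes were compared by Pearson correlation against 1000 shuffles of positions within chromosomes. Distances are between transcription starts, since the exon table gives no gene ends, where gene midpoints had been planned. Positions are mm9, as the tables give them. A reference genome of another build was not used.

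Named genes follow a rule set before the data were examined. It takes, among called genes with a mean level above the median of measured genes, the 10 largest increases and 10 largest decreases in exons and 5 of each in introns. It adds up to 4 called members of each list with the largest change, a fixed set of pluripotency, neural, adhesion, Xist and collagen genes, the 5 and 5 genes with the largest difference between exon and intron fold change, and the genes of the 3 most changed runs of at least 4 neighbours. Other genes are named as chosen after their values were seen. Some genes that the rule takes are not reported here.

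Alternatives fixed before the data were examined were filters on the mean of none and 10 RPKM, pseudocounts of 0.1 and 5, adjusted p thresholds of 0.01 and 0.1, a minimum log2 fold change of 1, each replicate left out in turn, the replicate number as a block, recentred fold changes, the other table, other correlations, and pairs of related or overlapping genes left out. Added after seeing the data were a subtraction of background, scaling of the columns to 1 median, a fit without variance trend, voom weights on recovered reads, comparisons by chromosome with chromosomes 1, 8, 12 and 19 left out, and the measures of silent genes and Y-linked genes. The background level of a column is its median over olfactory, vomeronasal, trace amine and bitter taste receptor genes. Of count-based models, voom was run on the recovered intron reads and edgeR and DESeq2 were not run. Separate technical libraries and alternatives that need exon counts or exon values per replicate were not run, since the tables do not hold them. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

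The limma comparison, the random lists, the correlation of adjacent genes and the recovery of reads were tested on simulated data, and the other comparisons were not. For the intronic comparison, 8811 genes were simulated with a dispersion of 0.02. There limma recovered 55% of genes changed by a log2 fold change of 1 and 100% of those changed by 2. It called 0.221% of unchanged genes. All simulated columns shared that dispersion and had no background or offset, unlike the data, so these rates may not hold for the data. In the exonic comparison of 12509 genes, 7% of simulated lists of 20 genes with no shift passed an unadjusted p of 0.05, and 97% with a shift of 2 log2 units did. For adjacent genes, a simulated r of 0.5 came back as 0.502, and independent values gave -0.00964. Recovery of reads found a single intron length for 94.8% of 2907 simulated genes, and the true length in 100% of those.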

Results

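Embryonic stem cells and neural progenitors derived from them were compared by sequencing of total RNA without ribosomal RNA, which keeps spliced transcripts and unspliced introns alike. The ESC line F1-21.6 is a cross of 2 mouse strains, and the NPC samples come from 1 clone of it. Each cell type had 2 biological replicates. Exon values were deposited as RPKM pooled per cell type with the authors' own test, so exon levels below are the authors' pooled values, in the order ESC then NPC, and carry no replicate spread. Intron values were deposited per biological replicate and rest on 6215905 and 7002634 recovered intron reads in ESC and 6130041 and 5536918 in NPC. The series title concerns the folding of chromosomes into functional domains, and the comparisons ask which genes changed between the cell types, whether exons and introns changed together, and whether changes ran along chromosomes.

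The pluripotency programme of ESC was all but gone in NPC, and a radial glial programme stood in its place. Pou5f1, the transcription factor at the centre of pluripotency, was at 1327 RPKM in ESC and 2.94 in NPC, Nanog at 406 and 2.07, Zfp42 at 492 and 1.26, and Esrrb at 347 and 1.27. Fabp7, a fatty acid binding protein of radial glia, was at 13.7 and 10684 RPKM, and Olig2, a transcription factor of ventral neural progenitors, at 0.686 and 448. The intermediate filament genes Vim (393 and 2741) and Nes (39.7 and 249) were expressed in both and higher in NPC. Cdh1, the cadherin of epithelia, fell from 235 to 1.503 RPKM, while Cdh2, the cadherin of neural tissue, rose from 2.65 to 98.4.

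In the authors' deposited table, 8277 of 12509 tested genes (66.2%) passed an adjusted p of 0.05, with 4040 higher and 4237 lower in NPC and a median log2 fold change of -0.07 over all tested genes. Changes of at least 4-fold were called in 1972 genes higher and 1846 lower. There were 333 genes above 10 RPKM in NPC and below 1 in ESC, and 371 the other way round. With a mean of at least 10 RPKM, 5473 of 8057 genes were called. The 1478 olfactory, vomeronasal and taste-type receptor genes are not known to be used by either cell type. They had a median of 0 RPKM in ESC and 0.279 in NPC. Of the 613 of them with an adjusted p, 36 were called higher and 1 lower. Among all genes with a mean below 1 RPKM, which the counts above leave out, 653 were called higher and 150 lower. Fold changes of genes near these levels in either cell type rest on few reads, and their calls leaned to NPC. Receptor genes also lay higher in NPC on introns, most of all in replicate 1 (below). The pooled exon values cannot show how much of this lean comes from that replicate.

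**Figure D1:**
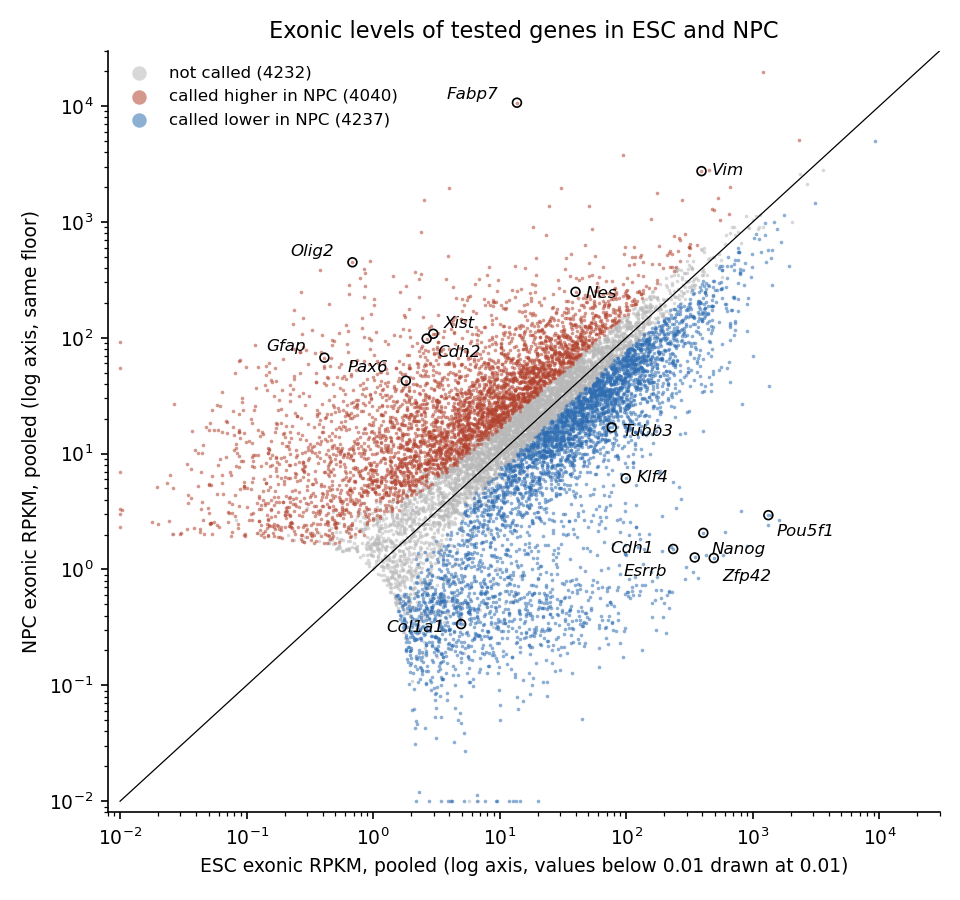
Pooled exonic RPKM of 12509 tested genes, ESC on the x axis and NPC on the y axis, both log scales with values under 0.01 drawn at 0.01. Each point is a gene, 4040 called higher in NPC in red and 4237 lower in blue, with Fabp7 and Olig2 far above the diagonal and Pou5f1 and Nanog far below it.

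By the authors' deposited table, the largest increases among called genes above the median expression were those of S100b (log2 fold change 9.80), E130114P18Rik (9.67), Pcdh11x (9.62), Fabp7 (9.43), Omg (9.22), Olig2 (9.18), Lmo3 (9.17), Lrrc4b (9.17), Gpm6b (9.11) and Pantr1 (9.10). S100b, a calcium binding protein of glia, reached 388 RPKM, and Gpm6b, a membrane protein of neural cells, 1554. The largest decreases in the authors' deposited table were those of Rpl10l (-9.63), Dppa5a (-9.39), Khdc3 (-9.37), Dppa3 (-9.33), Tdgf1 (-9.32), Tex19.1 (-9.27), Trap1a (-9.23), Tdh (-9.15), D7Ertd143e (-9.11) and L1td1 (-9.08). Dppa5a (1606 and 2.66 RPKM), Tdgf1 (1306 and 2.40) and L1td1 (1384 and 2.93) are transcripts of the pluripotent state. Tdh encodes threonine dehydrogenase, a metabolic enzyme of mouse ESC, and was at 193 and 0.385 RPKM. Rpl10l has a near-identical ribosomal protein copy on the X chromosome, so its value is uncertain.

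All 29 naive pluripotency genes fell, with a median log2 fold change of -8.26, and all 29 passed adjusted over the list alone. Klf4, at 99.2 and 6.12 RPKM, fell less than most. Of 15 formative and primed epiblast genes, which mark the next step of embryonic development, 3 rose and 9 fell, the same adjusted over the list alone (median -2.43). Nodal, a signal of the early embryo, fell from 77.1 to 0.350 RPKM, the methyltransferase Dnmt3b from 89.9 to 2.09, Grhl2 from 21.4 to 0.304 and Cldn6 from 30.8 to 0.445. All 9 tested 2-cell-like genes, active in the early cleavage embryo and in a few cells of ESC cultures, fell both over all genes and adjusted over the list alone (median -5.53). They include Zscan4d (19.3 and 0.155 RPKM), Zscan4c (5.36 and 0.0270), Tcstv1 (85.5 and 0.708) and Gm5662 (9.94 and 0.0912), whose near-identical copies make single values uncertain. Of 15 germline genes held silent by promoter methylation in somatic cells, 1 rose (Brdt, named after its value was seen) and 9 fell, and 1 and 11 adjusted over the list alone (median -4.01). Among them Tex19.1 fell from 93.4 to 0.174 RPKM and Sycp3 and Hormad1, proteins of the meiotic chromosome axis, from 43.0 to 1.047 and from 29.1 to 0.406. Rhox6, one of a family of near-identical copies, was at 9.60 and 0.161 RPKM. The medians of these lists lay below random lists of matched expression, with adjusted p = 0.000569 for the naive, 2-cell-like and germline lists and 0.00247 for the epiblast list. On introns, the limma camera test gave adjusted p = 0.665 with an estimated correlation for the naive, epiblast and 2-cell-like lists and 0.801 for the germline list, and the 3 germline genes tested there did not lie outside random lists (adjusted p = 0.236).

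All 33 tested neural progenitor and radial glia genes rose, also adjusted over the list alone, with a median log2 fold change of 4.80. Olig1 was at 0.846 and 391 RPKM, and Pax6, a regulator of the neural lineage, at 1.81 and 42.6. Of 17 astrocyte genes 14 rose and 2 fell (Clu and Gja1, named after their values were seen), the same adjusted over the list alone (median 4.94). They include S100b, Gfap (0.412 and 67.3 RPKM), the glial membrane protein Mlc1 (0.280 and 148), Sparcl1 (2.37 and 816) and the water channel Aqp4 (0.0684 and 18.99). Both lists lay above random lists with adjusted p = 0.000569, while camera on introns gave adjusted p = 0.665 with an estimated correlation for each. Of 18 neuronal genes, 5 rose and 10 fell, the same adjusted over the list alone, with a median of -1.48 and adjusted p = 0.0509 against random lists. Dcx (0.0639 and 33.8 RPKM) and Map2 (2.14 and 371), which bind microtubules, rose, while Stmn2 (160 and 0.792), the neurofilament gene Nefl (33.4 and 0.795) and the neuronal tubulin Tubb3 (76.8 and 16.8) fell. Of 7 oligodendrocyte genes, 3 rose and 2 fell, also adjusted over the list alone (median 0.98, adjusted p = 0.434). The myelin gene Cnp (11.2 and 203 RPKM) and the secreted enzyme Enpp2 (0.854 and 10.6) rose, and Myrf, the regulator of myelin genes, fell from 11.9 to 0.407. All 18 tested genes of the list of large conserved neural adhesion and synapse genes rose, the same adjusted over the list alone (median 5.56, adjusted p = 0.000569 against random lists; by camera on introns adjusted p = 0.665 with an estimated correlation). Cntn1 was at 0.232 and 130 RPKM, Lsamp at 0.0814 and 49.2, Nlgn1 at 0.0372 and 15.7 and Sorcs1 at 0.0617 and 25.6.

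Hox genes, which set position along the body axis, were nearly silent in ESC and expressed in the NPC clone. Of 18 tested, 17 rose and 1 fell (Hoxc13, named after its value was seen), the same adjusted over the list alone, with a median log2 fold change of 5.74 and adjusted p = 0.000569 against random lists. Camera on introns gave adjusted p = 0.665 with an estimated correlation for the Hox list and for the Notch list. Hoxa2 was at 0.155 and 43.4 RPKM, Hoxb2 at 0.0776 and 23.3, Hoxb8 at 0.0887 and 13.7 and Hoxa9 at 0.407 and 54.9. Of 20 genes of the Notch pathway, which maintains neural progenitors, 13 rose and 2 fell (Jag2 and Rbpj, named after their values were seen), the same adjusted over the list alone (median 2.76, adjusted p = 0.000569). The Notch target genes Hes5 (0.263 and 74.8 RPKM) and Hey1 (5.59 and 225), the coactivator Maml2 (0.445 and 28.8) and the receptor-modifying enzyme Lfng (0.961 and 30.3) rose. Of 20 cholesterol synthesis genes 18 rose and none fell, the same adjusted over the list alone (median 1.83, adjusted p = 0.000569 against random lists; by camera on introns adjusted p = 0.745 with an estimated correlation), among them Cyp51 (50.7 and 440 RPKM), Nsdhl (32.3 and 253), Dhcr7 (8.81 and 55.3) and the sterol sensor Insig1 (33.2 and 207).

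**Figure D2:**
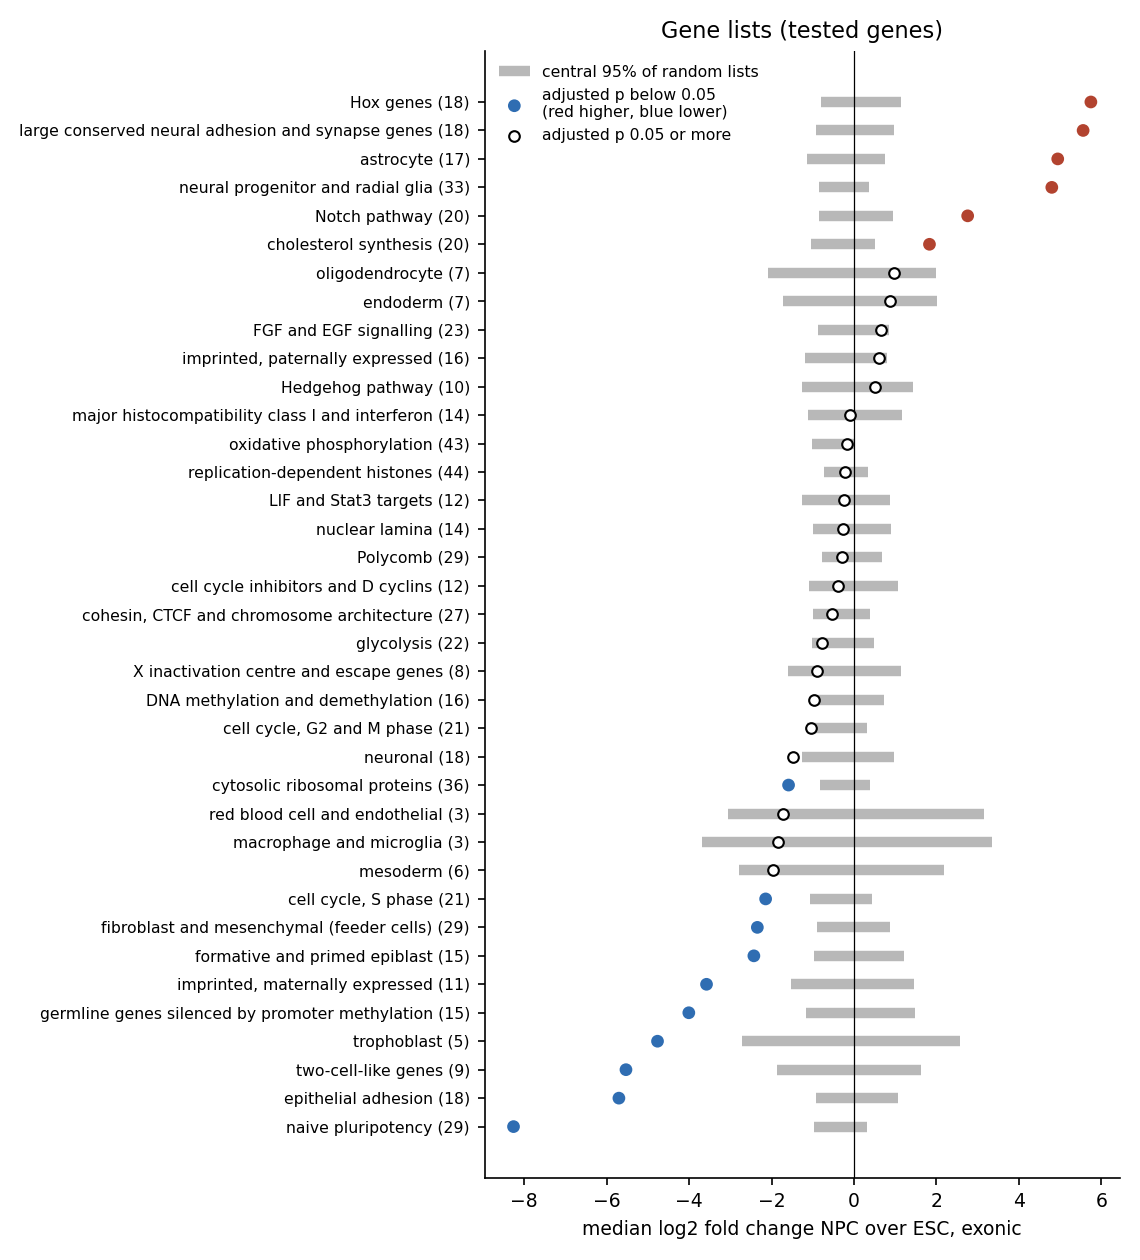
Median exonic log2 fold change of NPC over ESC of each list with at least 3 tested genes (points, number of genes in brackets) against the central 95% of random lists of matched expression (grey bars). Filled points passed the adjusted test, with Hox genes at 5.74 the highest and naive pluripotency at -8.26 the lowest.

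Genes of epithelial adhesion and of cell division fell. All 18 epithelial adhesion genes fell, also adjusted over the list alone (median -5.70, adjusted p = 0.000569), with camera on introns giving adjusted p = 0.6701 with an estimated correlation. Among them were Epcam (193 and 1.44 RPKM), the tight junction gene Cldn4 (86.7 and 0.424) and the protease inhibitor Spint2 (52.2 and 0.444). Of 21 S phase genes 20 fell and none rose, the same adjusted over the list alone (median -2.14, adjusted p = 0.000569), and by camera on introns adjusted p = 0.665 with an estimated correlation. The replication licensing genes Cdt1 (101 and 7.64 RPKM), Mcm5 (471 and 40.3) and Mcm3 (651 and 61.4) and the repair enzyme Ung (118 and 10.9) led the list. Of 21 genes of G2 and M phase 19 fell and none rose, the same adjusted over the list alone, with a median of -1.04 that did not lie outside random lists (adjusted p = 0.195). Ccnb1 was at 219 and 44.6 RPKM, Kif11 at 370 and 113, Aurka at 174 and 55.2 and Ccnb2 at 157 and 52.1. Of 12 cell cycle inhibitors and D cyclins, 3 rose and 6 fell, the same adjusted over the list alone (median -0.38, adjusted p = 0.615), and the median was 0.19 with a mean of at least 10 RPKM and 0.18 without a filter. Among these the inhibitor Cdkn2c rose from 1.72 to 120 RPKM, while Cdkn1a (41.2 and 2.88), Cdkn1c (15.6 and 1.48) and Cdk6 (9.38 and 0.522) fell. Of 36 cytosolic ribosomal protein genes, 1 rose (Rpl5, named after its value was seen) and 33 fell, and 1 and 34 adjusted over the list alone (median -1.59, adjusted p = 0.000569), and by camera on introns adjusted p = 0.805 with an estimated correlation. Rpl10a was at 39.7 and 4.24 RPKM, Rps28 at 69.2 and 7.71, Rpl17 at 19.9 and 3.11 and Rpl35 at 5.34 and 0.720. Processed copies of ribosomal protein genes elsewhere in the genome make these levels uncertain.

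Of 29 fibroblast and mesenchymal genes, fixed as markers of the feeder cells, 7 rose and 18 fell, and 7 and 20 adjusted over the list alone (median -2.34, adjusted p = 0.000569). On introns the 6 tested members did not lie outside random lists (median -0.76, adjusted p = 0.245), and camera gave adjusted p = 0.619 with its preset correlation and adjusted p = 0.880 with an estimated correlation. The smooth muscle and matrix genes Tagln (36.0 and 0.797 RPKM), Thbs1 (22.9 and 0.606) and Cthrc1 (12.4 and 0.358) fell, and so did Col1a1, the main collagen of fibroblasts, from 4.96 to 0.337. The summed RPKM of the list was nevertheless 810 in ESC and 2964 in NPC, most of it Sparc (447 and 2820), a matrix protein of glia and fibroblasts alike that was picked out after its values were seen. Of 5 trophoblast genes 4 fell and none rose, the same adjusted over the list alone (median -4.77, adjusted p = 0.00324): Krt18 (40.4 and 0.368 RPKM), Krt8 (10.5 and 0.1998), Tfap2c (17.3 and 0.216) and Ascl2 (4.00 and 0.309). Camera on introns gave adjusted p = 0.801 with an estimated correlation for the trophoblast list. The keratins stand in the epithelial list as well. Of 7 endoderm genes 4 rose and 2 fell, the same adjusted over the list alone, and the median (0.87) and the mean (-0.10) of the list differed in sign (adjusted p = 0.523). Dab2 (0.805 and 9.49 RPKM) and the basement membrane collagen Col4a1 (16.8 and 55.2) rose, and Hnf4a (7.12 and 0.250) and Lama1 (3.99 and 0.297) fell. With chromosomes 1, 8, 12 and 19 left out, an alternative chosen after seeing the data, the endoderm median was -1.56. Of 6 mesoderm genes, 2 fell, Myl7 (3.495 and 0.185 RPKM) and Kdr (1.54 and 0.6003), and 1 adjusted over the list alone (median -1.96, adjusted p = 0.432). Without a filter on the mean, 16 mesoderm genes had a median of -1.12 (adjusted p = 0.00789). All 3 tested red blood cell and endothelial genes fell, also adjusted over the list alone (median -1.73, adjusted p = 0.366), with Pecam1, a surface protein of endothelium and of ESC, at 45.4 and 0.346 RPKM and Tek at 11.4 and 3.89. Of 3 macrophage and microglia genes 2 fell, the same adjusted over the list alone (median -1.83, mean -0.80, adjusted p = 0.466), Cd68 (10.9 and 2.99 RPKM) and Itgam (1.72 and 0.490). None of the 58 clustered protocadherins and none of the 13 mitochondrially encoded genes was among the tested exon genes, so these lists gave no exon result. On introns 2 protocadherins, Pcdha1 and Pcdhgb8, were tested and rose in limma, the same adjusted over the list alone. Of 37 lists with at least 3 tested genes, 16 passed against random lists, 6 higher and 10 lower in NPC.

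Introns, which can mark unspliced and newly made transcripts, gave the same contrast with replicate error. The columns were not scaled, so the NPC spread includes an offset between its replicates. The median log2 difference of replicate 2 over replicate 1 was 0.42 in NPC and 0.01 in ESC. Reads at the level of genes silent in ESC would make up 69.2% of the intron reads of NPC replicate 1 (below). The NPC spread is therefore not biological variation alone. Pou5f1 introns were at 145 ± 11.3 RPKM in ESC and 0.293 ± 0.414 in NPC (SD, n = 2 each). Fabp7 introns were at 0.442 ± 0.00434 and 290 ± 190 RPKM, and Olig2 introns at 0.111 ± 0.157 and 202 ± 115 (SD, n = 2 each). In limma on log2(RPKM + 1), the largest increases of called genes above the median level were Fabp7 (log2 fold change 7.49, SE 0.783, adjusted p = 4.5e-05), Olig2 (7.396, SE 0.700, adjusted p = 3.3e-05), Fos (5.68, SE 0.867, adjusted p = 0.00034), Hey1 (5.47, SE 0.706, adjusted p = 0.00012) and Egr1 (4.86, SE 0.649, adjusted p = 0.00015). Fos and Egr1, immediate early genes of growth factor signalling, rose in exons too, from 24.3 to 1363 and from 19.3 to 492 RPKM. Without ESC replicate 1 or 2, Egr1 was at 4.99 or 4.73 and Hey1 at 5.39 or 5.55, so the fold changes stayed while the calls were lost. In those fits the spread comes from the NPC replicates alone. Among called genes above the median level, the largest intron decreases in limma were Pou5f1 (-6.86, SE 0.649), Pramel7 (-5.81, SE 0.603), Trh (-5.23, SE 0.494), Zfp42 (-5.21, SE 0.527) and L1td1 (-5.21, SE 0.550). Of the fixed genes, Nanog (-4.84), Esrrb (-3.18), Cdh1 (-2.22) and Tubb3 (-1.72) fell and Gfap (2.33), Pax6 (1.92), Xist (1.41) and Cdh2 (1.40) rose. Klf4 (-0.88, limma adjusted p = 0.239), Vim (1.252, adjusted p = 0.172) and Nes (0.61, adjusted p = 0.44) did not pass. The intron value of Nes was -0.10 without NPC replicate 2 and 1.32 without NPC replicate 1. Without NPC replicates 1 and 2 in turn, Klf4 was at -0.43 and -1.33 and Vim at 1.92 and 0.59. These fits hold no spread between NPC replicates, so they do not overturn the full test.

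Of 8811 genes tested on introns, limma called 4165, 1167 higher and 2998 lower in NPC, so that 28.0% of calls were higher. The median over all tested genes was -0.43, and scaling all columns to 1 median brought it to -0.05. After that scaling limma called 4582 genes, 2260 higher and 2322 lower (49.3% higher), of which 3326 were called in the same direction without it. With receptor-gene background subtracted as well, it called 5517 genes, 2605 higher and 2912 lower (47.2% higher). Both alternatives were added after seeing the data. Directions of single genes near the median therefore depend on the scaling. Groups did not overlap in 77.4% of genes, with both NPC values above both ESC values in 1931 genes and below in 4889. Random order gives 33.3%. These columns were not scaled and the median fold change was -0.43, so 33.3% is not the value without change.

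The ESC replicates differed less than the NPC replicates. Across 8811 genes, log2 values correlated with r = 0.985 between ESC replicates and 0.923 between NPC replicates, and the median absolute log2 difference was 0.10 and 0.48. In 2658 genes below 0.1 RPKM in both ESC replicates, the median intron level was 0.891 RPKM in NPC replicate 1 and 0.146 in NPC replicate 2, against 0.0609 and 0.0108 in ESC replicates 1 and 2. Receptor genes (240 with introns) had medians of 0.748 and 0.0829 RPKM in NPC and 0.0287 and 0 in ESC. Without NPC replicate 1 limma called 6192 genes, 2344 higher and 3848 lower, and 4093 of the original calls kept their direction. Without NPC replicate 2 it called 6574 (1279 higher and 5295 lower), and without ESC replicate 1 or 2 it called 1686 or 1594.

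**Figure D3:**
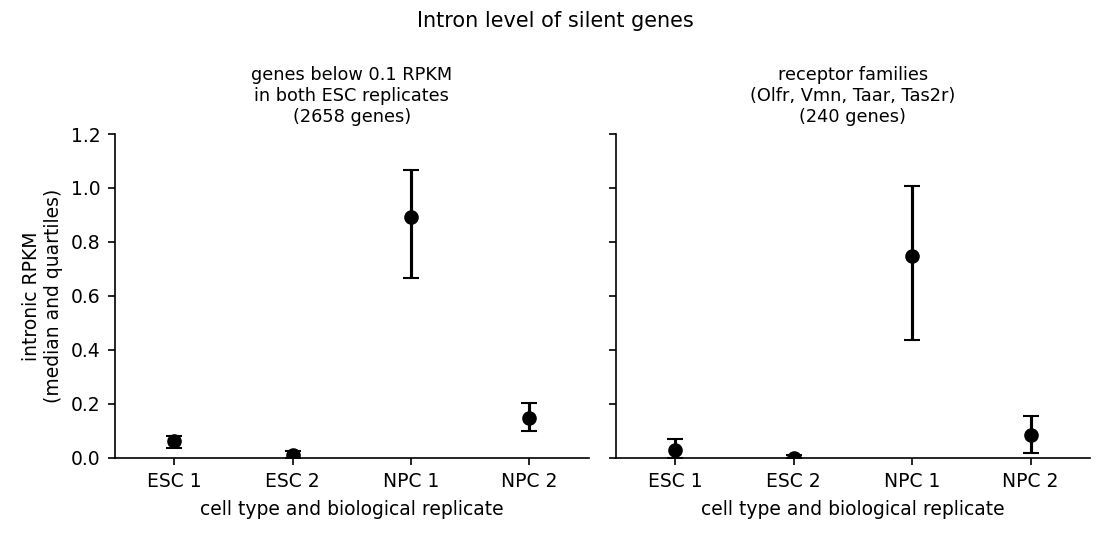
Intron RPKM (y axis) per biological replicate (x axis) for 2658 genes below 0.1 RPKM in both ESC replicates and for 240 receptor genes, as medians with bars to the quartiles. NPC replicate 1 stands at 0.891 and 0.748 RPKM, NPC replicate 2 at 0.146 and 0.0829.

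Against random lists 14 of 31 lists passed on introns, 7 higher and 7 lower. The germline (median -0.98, adjusted p = 0.236), fibroblast (-0.76, adjusted p = 0.245) and maternally expressed imprinted lists (-1.07, adjusted p = 0.245), which passed on exons, did not pass on introns, but the maternal list did after background subtraction with scaling (-1.18, adjusted p = 0.0393). FGF and EGF signalling, which did not pass on exons with the main filter, passed on introns (0.60, adjusted p = 0.00248), with 0.21 (adjusted p = 0.00789) without NPC replicate 2. For FGF and EGF signalling camera gave adjusted p = 0.110 with its preset correlation and adjusted p = 0.805 with an estimated correlation. By limma, 25 of 26 naive pluripotency genes fell (median -3.15) and 9 of 9 epithelial adhesion genes, the same adjusted over the list alone. Of 22 S phase genes 19 fell, and 20 adjusted over the list alone (median -1.86), and of 55 ribosomal protein genes 47, and 51 adjusted over the list alone (median -2.77). Of 26 neural progenitor genes 22 rose and 0 fell (median 2.16), and of 12 astrocyte genes 8 rose and 1 fell (1.90). Of 16 Hox genes 14 rose and 2 fell (2.04), and of 16 Notch genes 13 rose and 1 fell (1.52). Adjusted over the list alone, the counts of these lists were the same. Of 21 cholesterol synthesis genes 11 rose, and 13 adjusted over the list alone, and 21 rose without NPC replicate 1. Without ESC replicate 1 and without ESC replicate 2 limma called 1 and 1 of these higher, 0 and 0 ribosomal protein genes lower (medians -2.79 and -2.80), 12 and 12 S phase genes lower, 15 and 14 neural progenitor genes higher and 7 and 7 Notch genes higher. The medians of these lists kept their sign after scaling, after background subtraction with scaling and without each replicate. The limma camera test passed 13 of 31 lists with its preset correlation and 0 with an estimated one, where 0 passed even unadjusted and the smallest unadjusted p was 0.106. The estimated correlation rests on 2 replicates per cell type, and with it even the naive list, 25 of 26 lower, did not pass. A list that failed this version is therefore not shown to be unchanged. For the naive pluripotency, epiblast, 2-cell-like, neural progenitor, astrocyte, Hox, S phase, Notch and large neural adhesion lists, camera gave adjusted p = 0.665 with an estimated correlation. It gave adjusted p = 0.6701 for epithelial adhesion, 0.745 for cholesterol synthesis, 0.805 for ribosomal proteins and 0.886 for G2 and M phase, each with an estimated correlation.

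Exon and intron changes went together gene by gene. Across 8380 genes in both tests, the log2 fold changes correlated with Pearson r = 0.804 and Spearman rho = 0.831. Both measures come from the same libraries, so differences between samples enter both and independent calls are no strict baseline. Of 3271 genes called in both, 98.3% had the same direction, 1028 higher and 2187 lower, where independent calls would give 309.7 and 1058. Another 52 were higher in exons and lower in introns and 4 the reverse (Acyp2, Alkbh4, Dusp4 and Maff, named after their values were seen), 2205 were called in exons alone and 673 in introns alone. The authors' deposited table put the exon fold change farthest above the intron one for S100b (difference 8.27), Omg (7.71), Lsamp (7.42), Cntn1 (7.36) and Gpm6a (7.21), genes of glia and neural adhesion with low intron levels. The exon change in the authors' deposited table lay farthest below the intron change for Trap1a (-7.95), Lefty2 (-7.68), Khdc3 (-7.48), Crip1 (-7.03) and Tcl1 (-7.01). The intron scale of log2(RPKM + 1) limits the fold change of low genes, so these differences are not measures of RNA stability.

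Over all tested exon genes, those on the X chromosome were lower in NPC than autosomal ones. Xist, the RNA that coats the inactive X, was at 2.99 and 108 RPKM, and its antisense partner Tsix at 19.8 and 1.14. The 2 genes overlap, and whether counting used strand is not given in the sources used here, so both values are uncertain. Jpx, an activator of Xist, was at 0.206 and 3.19 RPKM, and Rlim at 396 and 140. Of 8 tested genes of the inactivation centre and genes that escape inactivation, 2 rose and 6 fell, the same adjusted over the list alone (median -0.91, adjusted p = 0.473). The median log2 fold change of 493 X-linked genes was -0.35, against -0.05 for 11997 autosomal genes, a difference of -0.30 (permutation p = 0.00143). With a mean of at least 10 RPKM the difference was -0.16 (permutation p = 0.122) and the call ended. On introns it was -0.17 (permutation p = 0.00867), and without NPC replicate 1 it was -0.15 (permutation p = 0.0358). Adjusted over the 20 chromosomes, the intron permutation p of X was 0.0373 with all replicates and 0.119 without NPC replicate 1.

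Several autosomes were shifted by as much as the X, a comparison made after seeing the data. Relative to the other autosomes, the median log2 fold change of chromosome 12 was 0.46 higher and that of chromosome 6 0.33 higher, while chromosome 8 lay at -0.50, chromosome 19 at -0.37 and chromosome 1 at -0.23. Permutation tests adjusted over the 20 chromosomes gave p = 0.0002 for chromosome 8, 0.0003 for chromosome 12, 0.0016 for chromosomes 6 and 19, 0.0058 for X, 0.0104 for chromosome 1 and 0.0421 for chromosome 3 (0.21 higher). Introns without NPC replicate 1 gave 0.43 for chromosome 12, 0.27 for chromosome 6, -0.35 for chromosome 8, -0.24 for chromosome 19 and -0.27 for chromosome 1, while chromosome 3 (0.12, adjusted p = 0.167) and X (-0.15, adjusted p = 0.119) did not pass there. With chromosomes 1, 8, 12 and 19 left out of the autosomes, the X lay at -0.33 (permutation p = 0.00027).

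**Figure D4:**
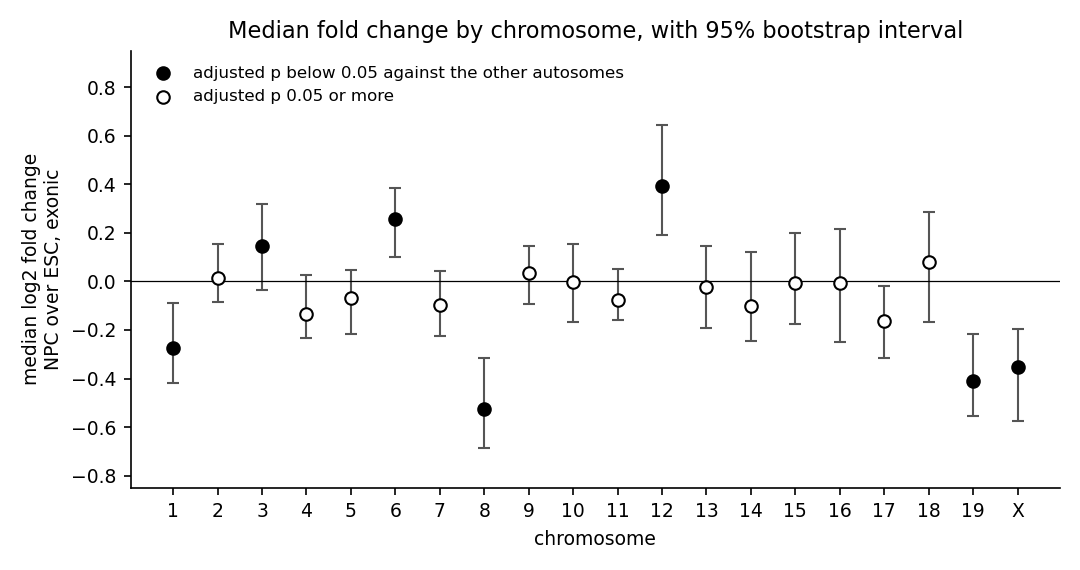
Median exonic log2 fold change of NPC over ESC (y axis) of tested genes by chromosome (x axis), with 95% bootstrap intervals and filled points where the adjusted p against the other autosomes is below 0.05. Chromosome 12 is the highest at 0.39 and chromosome 8 the lowest at -0.52.

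Neighbouring genes changed alike more often than shuffled ones. The runs of neighbours with the largest mean change were the Zscan4 cluster on chromosome 7 (mm9 transcription starts 11384414 to 11896031), the Nanog locus on chromosome 6 and a neural run on the X. Zscan4a, Zscan4c, Zscan4d and Zscan4e had a mean log2 fold change of -7.59 in the authors' deposited table, with Zscan4e listed at 0 in NPC, and are near-identical copies with uncertain values. Gdf3, Dppa3, Nanog and Slc2a3 on chromosome 6, from 122560089 to 122692763, had a mean of -7.32 in the authors' deposited table. Chrdl1, Pak3, Capn6 and Dcx on X, from 139828805 to 140367667, had a mean of 6.69 in the authors' deposited table, with Capn6 at 0.858 and 361 RPKM.

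Over 12470 adjacent pairs of tested genes, fold changes correlated with r = 0.150, against 0.00809 after shuffling positions within chromosomes (95% of shuffles between -0.00952 and 0.0257). The permutation p of the shuffles was 0.001, the smallest that 1000 of them can give. Leaving out pairs with related names gave r = 0.128, and overlapping pairs 0.148. By distance between transcription starts, r was 0.156 within 50 kb, 0.0657 from 50 to 100 kb, 0.0517 from 100 to 200 kb and 0.0205 from 200 to 500 kb (adjusted p = 0.0084). From 500 to 1000 kb it was 0.0105 (adjusted p = 0.45), from 1000 to 2000 kb 0.0162 (adjusted p = 0.0084) and from 2000 to 5000 kb 0.0114 (adjusted p = 0.0315). On introns r was 0.193, 0.0714 and 0.0478 over the 3 shortest distances (adjusted p = 0.0035, 0.0035 and 0.0105). From 200 to 500 kb the intron r was 0.0139, below the shuffled mean of 0.0177 (adjusted p = 0.602). From 1000 to 2000 kb it was 0.0242 (adjusted p = 0.2855), above the shuffled mean of 0.0184 as in exons. It lay within the shuffled range of 0.00908 to 0.0281. The exon results at these 2 distances did not pass on introns. With fewer pairs there (50658 against 91883 from 1000 to 2000 kb), this does not show them absent. From 2000 to 5000 kb the intron r was 0.0259 (adjusted p = 0.0105), above the shuffled mean of 0.0161 as in exons. There were 308 runs of at least 4 neighbours called in 1 direction, 143 higher and 165 lower with 1455 genes in all, against 211 after shuffling (185 to 235, permutation p = 0.001).

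**Figure D5:**
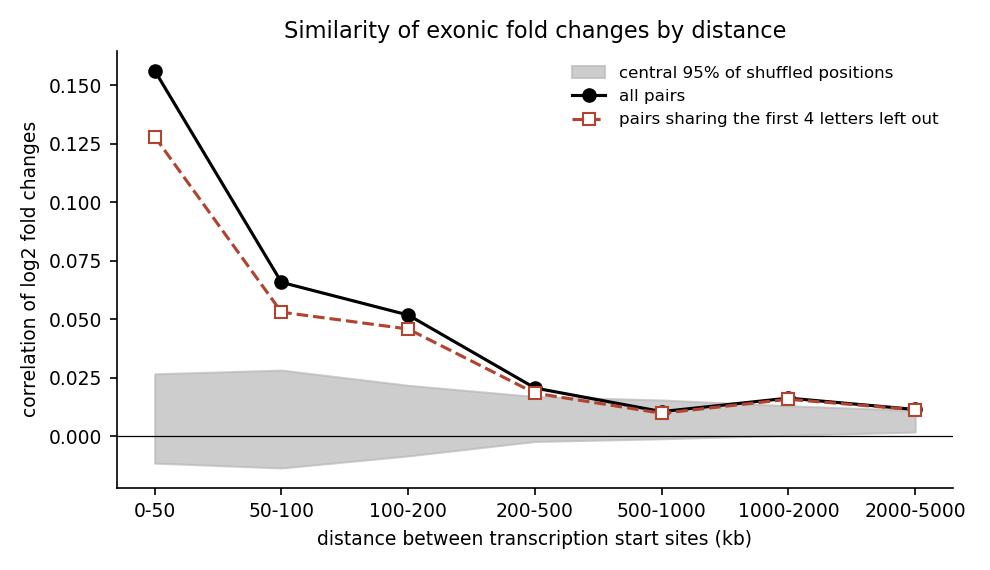
Pearson r of exonic log2 fold change between pairs of tested genes (y axis) by distance between transcription starts in kb (x axis), for all pairs (black), with pairs of related names left out (red), and the central 95% of shuffled positions (grey band). The value for all pairs falls from 0.156 within 50 kb to 0.0105 between 500 and 1000 kb.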

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

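All tests in this part were chosen after the results were seen, as was the limit of 3 Mb on the gene spans used for shares of reads. With 2 replicates per cell type, no sample was tested for standing apart from its group.

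Intron reads in receptor genes, data outside the main comparisons that enter the background subtraction, had a median of 0.748 RPKM in NPC replicate 1, above the 0.0287 and 0 RPKM of ESC replicates 1 and 2, and 0.0829 in NPC replicate 2. Over 18626 genes with spans under 3 Mb, reads at the median level of ESC-silent genes would make up 69.2% of the recovered intron reads of NPC replicate 1, 11.1% of NPC replicate 2, and 4.66% and 0.826% of ESC replicates 1 and 2. Transcription of these genes in neural progenitors should appear in both NPC replicates, but the level in replicate 2 was 0.164 of that in replicate 1, and unspliced RNA of expressed genes would leave receptor genes alike, but their level was 9.02 times higher in replicate 1 than in replicate 2. A candidate explanation that stays open is genomic DNA in the libraries of NPC replicate 1, since the silent genes of the X and of autosomes were at like levels there (ratio 1.02, 95% bootstrap interval 0.860 to 1.11). The extraction day and any DNase step are not given in the sources used here.

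Y-linked introns held 160 reads in the ESC replicates (79 and 81), data outside every comparison, against 50 and 10 in NPC replicates 1 and 2. Pooled exon levels in ESC and NPC were 3.41 and 0.0534 RPKM for Eif2s3y and 2.23 and 0.0466 for Ddx3y, with Usp9y the other way at 0.0163 and 1.08, all picked after their values were seen. A Y chromosome in every ESC would need Y copies nearer the level of their X partners than the ratio of Eif2s3y to Eif2s3x, 0.0743. That was the highest ESC ratio. The others were 0.00550 for Uty, 0.00177 for Ddx3y, 0.000997 for Kdm5d and 3.8e-05 for Usp9y. Why the ratios differ between pairs was not tested. Misplaced reads of the X partners would give NPC and ESC like ratios. In each of 5 pairs the ratios differed by at least 12.3 times, higher in ESC in 4. Usp9y, a pair added last, went the other way, with an ESC ratio 0.00570 of the NPC ratio. Usp9y introns had more reads in ESC (22 and 26) than in NPC (14 and 5). Misplaced reads are therefore not excluded for Usp9y. Male feeder cells may be the source, but only 2 of 3 fibroblast collagens were called lower in NPC in the authors' deposited table (Col1a1 and Col3a1, with Col1a2 at an adjusted p of 0.0706), so feeders and a minority of Y-bearing ESC cannot be told apart. Over 7 Y-linked genes NPC replicate 1 had 30 intron reads, where 2552 would lie at the level of its silent genes. The reads due at that level were not worked out for the ESC replicates. Their Y-linked intron reads are therefore not shown to exceed the level of their silent genes.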

How the results depend on the processing

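Scaling, background subtraction, the fit without variance trend, voom weights, the omission of chromosomes 1, 8, 12 and 19 and the exon to intron correlation without an NPC replicate were chosen after seeing the data. Of the alternative values of the main results, 75 kept their direction and their side of the threshold or stayed within 1.5 times the count, and 20 were weaker, 5 stronger and 2 moved. For single genes and lists 863 kept theirs, 27 lost the test, 16 passed it and 17 turned sign. Exons gave 5473 calls, 2534 higher, with a mean of at least 10 RPKM, where fewer genes (8057) were tested. Introns gave 1166 calls (226 higher, 940 lower) without a filter and 420 (48 and 372) with a mean of at least 10 RPKM over 903 genes. At an adjusted p of 0.01 they gave 2699 (1895 lower), and 2720 (702 higher) at a log2 fold change of at least 1, both stricter by construction. Without variance trend 753 rose, after scaling 2260 and after background subtraction with scaling 2605, and the cause was not tested. With each replicate left out, calls ranged from 1594 to 6574, higher from 488 to 2344 and lower from 1106 to 5295, where a lone sample was assumed to vary like the other group. The exon to intron correlation was 0.6701 without a filter and 0.697 with a pseudocount of 5, and the X difference was -0.16 (permutation p = 0.122) with a mean of at least 10 RPKM. The cause of these was not tested.

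Signs turned for cell cycle inhibitors and D cyclins (0.18 without a filter, 0.19 with a mean of at least 10 RPKM) and, without chromosomes 1, 8, 12 and 19, for endoderm (-1.56), oxidative phosphorylation (0.0670), LIF and Stat3 targets (0.14) and histocompatibility genes (0.22), none past the test in either setting. On introns, medians turned sign after scaling and after background subtraction with scaling for Polycomb (0.0859 and 0.0871), cell cycle inhibitors and D cyclins (0.18 and 0.13) and LIF and Stat3 targets (0.29 and 0.28). With each replicate left out the intron medians ranged from -0.48 to 0.16 for the inhibitors and D cyclins, -0.39 to 0.18 for LIF and Stat3 targets, -0.25 to 0.53 for paternally expressed and -0.12 to 0.21 for Hedgehog genes, none past the test. Intron Nes ranged from -0.10 to 1.32 with each replicate left out and was below 0 without NPC replicate 2 alone. The cause was not tested. Of the other list medians 5 passed and 4 lost the test under an alternative, and 3 intron medians passed, glycolysis without NPC replicate 1 or 2 (adjusted p = 0.0207 and 0.0322) and the maternally expressed list after background subtraction with scaling, and of the intron values of named genes 8 passed and 23 lost it.

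With the replicate number as a block, introns gave 3777 calls (1145 higher, 2632 lower), 3709 of them shared. Deviations of same-numbered replicates correlated with r = 0.0190 over 8811 genes, so the numbers are not shown to pair the samples. Not run were edgeR and DESeq2 with its size factors, which were not used on the recovered intron reads either. Separate technical libraries and exon alternatives by replicate, block or pseudocount were not run, since the tables hold no such values; lists without each replicate were run on introns alone. Recentring keeps the p-values and so the counts by construction, and no symbol was repeated. Median intron reads per gene were 67 to 119, and a gene of 10 kb with 0 reads may lie at up to 0.0461 to 0.0578 RPKM.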

Other observations

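The comparisons by chromosome and the tests of copy number were chosen after the shifts were seen, while the tests on windows of chromosomes 8 and 12 were set before the values of windows were seen. The lists were fixed before the data were examined.

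Imprinted genes are expressed from 1 parental copy. Of 11 maternally expressed genes 2 rose (Gatm and Ppp1r9a, named after their values were seen) and 6 fell, the same adjusted over the list alone (median log2 fold change -3.58, adjusted p = 0.00106 against random lists; by camera on introns adjusted p = 0.745 with an estimated correlation), with H19 at 208 and 0.603 RPKM in ESC and NPC, Phlda2 at 14.5 and 0.215 and Grb10 at 22.5 and 0.296. Of 16 paternally expressed genes 7 rose and 5 fell, and 8 and 5 adjusted over the list alone (median 0.61, adjusted p = 0.194), with Nnat at 6.83 and 324 RPKM, Peg12 at 4.42 and 89.1 and Zdbf2 at 24.9 and 0.638. Igf2r (67.5 and 3.23) and the antisense RNA Airn (0.197 and 5.82) overlap, so both are uncertain. The difference between the lists was not tested. Without a filter on the mean, the maternal median was -0.13 (adjusted p = 0.663). On introns it was -1.07 (adjusted p = 0.245), and -1.18 (adjusted p = 0.0393) after background subtraction with scaling.

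Genes of DNA methylation and chromatin changed in both directions. Of 16 genes of DNA methylation and demethylation 4 rose and 9 fell, the same adjusted over the list alone (median -0.96, adjusted p = 0.129), among them Dnmt3l, a cofactor of methyltransferases in germ cells and ESC, at 231 and 0.640 RPKM, Apobec2 at 32.6 and 0.304, and Zfp57, which protects imprints, at 304 and 22.8. With a mean of at least 10 RPKM this list had a median of -1.29 (adjusted p = 0.0237), while camera on introns gave adjusted p = 0.110 with its preset correlation and adjusted p = 0.801 with an estimated correlation. Of 29 Polycomb genes 7 rose and 14 fell, the same adjusted over the list alone (median -0.29, adjusted p = 0.615), with Cbx7 at 39.5 and 2.68 RPKM, Mtf2 at 315 and 23.1 and Eed at 486 and 51.9, all lower. Of 27 genes of cohesin, CTCF and chromosome architecture 3 rose and 13 fell, the same adjusted over the list alone (median -0.54, adjusted p = 0.615). The cohesin subunit Smc3 (469 and 128 RPKM), Esco2 (161 and 41.5) and the condensin subunit Smc2 (248 and 85.5) fell, and Satb1, an organiser of chromatin loops, rose from 0.699 to 25.4. Of 14 genes of the nuclear lamina 5 rose and 6 fell, the same adjusted over the list alone, with median (-0.26) and mean (0.02) of opposite sign (adjusted p = 0.798). Syne2 (3.29 and 37.6 RPKM) and Syne1 (1.49 and 10.1) rose, and Lmna (54.4 and 12.7) and Banf1 (121 and 37.1) fell. Of 44 replication-dependent histone genes, near-identical copies with uncertain values, 6 rose and 9 fell, and 6 and 8 adjusted over the list alone (median -0.23, adjusted p = 0.943), with Hist1h1a at 1948 and 418 RPKM and Hist2h2ab at 14.0 and 64.2.

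Metabolic and signalling lists mostly split by member. Of 22 glycolysis genes 6 rose and 13 fell, the same adjusted over the list alone (median -0.78, adjusted p = 0.272), with the kinase Pfkp at 136 and 1.12 RPKM, the lactate exporter Slc16a3 at 40.8 and 0.631 and the glucose transporter Slc2a3 at 401 and 15.7, and Aldoc, the brain aldolase, at 8.26 and 288. Of 43 oxidative phosphorylation genes 1 rose (Ndufa3, named after its value was seen) and 9 fell, and 0 and 6 adjusted over the list alone (median -0.17, adjusted p = 0.324), such as Cox7b (843 and 381 RPKM) and Cox5a (148 and 73.1), and with chromosomes 1, 8, 12 and 19 left out the median was 0.0670. Of 10 Hedgehog genes 5 rose and 3 fell, the same adjusted over the list alone, with median (0.52) and mean (-0.19) of opposite sign (adjusted p = 0.587): the target gene Gli1 (10.5 and 0.180 RPKM) fell, and the surface proteins Gas1 (2.03 and 84.3) and Cdon (3.45 and 31.6) rose. Of 23 genes of FGF and EGF signalling 10 rose and 10 fell, the same adjusted over the list alone, again with median (0.65) and mean (-0.20) of opposite sign (adjusted p = 0.195, and 0.00341 with a median of 1.67 at a mean of at least 10 RPKM). Camera on introns gave this list adjusted p = 0.110 with its preset correlation and adjusted p = 0.805 with an estimated correlation. The ligands Fgf4 (128 and 0.656 RPKM) and Fgf17 (22.2 and 0.465) fell, and the receptors Egfr (3.23 and 158) and Fgfr3 (1.14 and 39.5) rose. Of 12 LIF and Stat3 targets 3 rose and 6 fell, the same adjusted over the list alone (median -0.25, adjusted p = 0.970), with Tfcp2l1 at 293 and 0.827 RPKM, Pim1 at 40.5 and 1.92 and Pim3 at 84.0 and 9.55, and the median was 0.14 without chromosomes 1, 8, 12 and 19. Of 14 genes of major histocompatibility class I and interferon 4 rose and 4 fell, the same adjusted over the list alone (median -0.10, adjusted p = 0.922, and a median of 0.22 without those chromosomes). Ifitm1 (69.5 and 0.257 RPKM) and Bst2 (23.7 and 0.0802) fell, and Ifit3 (0.201 and 2.95) and Tap2 (1.43 and 11.7) rose.

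The shifts of chromosomes 12 and 8 may reflect whole-chromosome copy number in cultured cells, a hypothesis. Introns of silent genes were read as a measure of DNA. For NPC replicate 1 the silent genes were those below 0.1 RPKM in both ESC replicates. For ESC replicate 1 they were another set, low in ESC replicate 2 and NPC replicate 2. Levels in NPC replicate 1 lay 1.23 times higher on chromosome 12 than on other autosomes (95% bootstrap interval 1.09 to 1.33). Levels in ESC replicate 1 lay 1.42 times higher on chromosome 8 (1.29 to 1.53). Over the 17 autosomes other than 8 and 12, the exon shift correlated with the log2 ratio of those levels, NPC replicate 1 to ESC replicate 1, with r = 0.808 (permutation p = 0.00018; Spearman rho 0.534, p = 0.0286), over all 19 with r = 0.892 (p = 1e-05; rho 0.667, p = 0.00239), and without the 2 farthest chromosomes with r = 0.775 (p = 0.00024; rho 0.534, p = 0.0294). Most 10 Mb windows lay on the side of the shift, 83.3% (10 of 12) above the other autosomes on chromosome 12 and 84.6% (11 of 13) below on chromosome 8. That is more than was predicted for a few gene clusters. It falls short of the share set beforehand for setting them aside, so this cause stays open. Regulation of these chromosomes in neural progenitors was not tested, and the reading of introns as DNA rests on the open explanation of background in NPC replicate 1. The like levels of X and autosomes that left DNA open in NPC replicate 1 (ratio 1.02) were not found in ESC replicate 1. Its X to autosome ratio of silent genes was 0.695 (95% bootstrap interval 0.601 to 0.776). DNA is therefore not shown to be the source there, which limits the chromosome 8 ratio and the correlations.

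The same measure in ESC replicate 1 was 1.203 for chromosome 1, 1.39 for chromosome 19 and 0.695 (0.601 to 0.776) for X over autosomes. Chromosome 6, with an exon shift of 0.33, was at 1.02 in NPC replicate 1 and 0.813 in ESC replicate 1. The X was left out of the correlations, and its measures had opposite signs. The log2 ratio of its silent genes was 0.55, NPC replicate 1 to ESC replicate 1, and its exon difference was -0.30. Xist was higher in NPC (2.99 and 108 RPKM in ESC and NPC, uncertain values). Read as DNA, the silent genes would put the X higher in NPC, opposite to its exon difference. That measure used 1 replicate per cell type, and DNA is not shown to be its source in ESC replicate 1. It therefore does not settle copy number on the X, and inactivation was not tested.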
